A study of Mus musculus with 8 samples.

How the data were processed

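The series holds 8 one-colour Agilent arrays of the mouse 8x60K design, 1 per RNA sample, with total RNA labelled with Cy3, per the labels. The 4 groups are 70Z/3 and '18-81' cells with a pre-miR-125b duplex or the miR-Neg control, with replicates 1 and 2 in each, taken from the sample titles. Per the labels' protocols, duplexes were used at 10 nM with a lipid reagent, medium was changed at 8 h, RNA was taken at 48 h with a column kit, 0.2 µg was labelled and the RNA integrity number was 9. Per the series' design text, the 8 samples come from 2 independent experiments.

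Per the file headers, the authors scanned 1 slide that holds all 8 arrays and extracted intensity values with Agilent Feature Extraction 10.7.3.1, and probe positions refer to mm9. The processed intensity in the deposited scanner files is background-subtracted and spatially detrended by that software, per the file headers. Slide position follows the design: the first row of the slide holds replicate 1 of the 4 groups, the second row replicate 2, and each column holds 1 group, so column and group cannot be told apart. The deposited series table holds linear intensity values of the same arrays after a normalization between arrays by the authors, whose method is not given in the sources used here. Its columns share the maximum 650812.1375, have medians from 14.64 to 14.71, are not centred by gene, and correlate with the scanner values at r between 0.9974 and 1 on the log2 scale. It was used as an alternative.

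Each file holds 62976 spots, of which 59305 are not controls, for 55681 probes. Control spots and spots with an outlier call were left out (140 to 203 spots with such a call per array), no spot was saturated, and spots of a probe were averaged. Values are log2 of the processed intensity minus the array's 75th percentile. Probes were named through the RefSeq gene table for GRCm38.p6, used for names only: 26413 by accession, 3859 by symbol and 735 by an older symbol, while 24674 kept the file's name. A gene was tested if a probe was well above background on both arrays of at least 1 group, and the probe with the highest mean stood for the gene, which left 18789 genes, 13708 of them with a symbol in the table. Another probe of the gene is mentioned where it disagreed.

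limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 8 arrays, so that the groups share 1 estimate of the spread, with empirical Bayes moderation (prior degrees of freedom 3.83, prior standard deviation 0.355) and Benjamini-Hochberg adjustment at 0.05. The comparisons were miR-125b against miR-Neg in 70Z/3, in '18-81' and averaged over both, the difference of these effects ('18-81' minus 70Z/3), and '18-81' against 70Z/3 under miR-Neg. The median of all genes differed by −0.13 in 70Z/3, 0.03 in '18-81' and −0.05 on average with the 75th percentile, and by −0.01, 0.02 and 0.01 after quantile normalization. The shift of a gene list is therefore given relative to the median of all genes. Where a gene was not well above background on any array of the dimmer group, the difference is given as a bound, from the mean of the brighter group against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. No fold is given where the bound is under 1 or neither group was above background.

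Before the data were examined, 18 gene lists were fixed from general knowledge: reported miR-125b targets, p53 pathway, apoptosis regulators, B-cell precursor, plasma cell differentiation, interferon response, G2/M, S-phase, Myc and nucleolar, NF-kappaB response, microRNA pathway, unfolded protein and stress response, cholesterol synthesis and glycolysis genes, and T-cell, myeloid, erythroid and stromal markers. The design, the alternatives and the rule for named genes were fixed at the same time. Lists were tested with camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the 18 lists, with an estimated correlation and with fry as alternatives. Named genes were the 10 largest changes per direction among genes past the threshold whose arrays do not overlap, filled up with the smallest p-values where fewer than 10 passed, 5 per direction for the difference of effects, up to 4 members per list, the B-cell precursor genes past the threshold between the lines, and 15 genes from work on miR-125b, p53 and B-cell maturation that were always to be reported. Further members of the lists were picked as examples after their values were seen. Some genes that the rule names are not reported here, and counts of genes include them.

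Replicates with the same number deviated together from their group means (r between 0.37 and 0.65 over the 6 pairs of groups), and the design text names 2 independent experiments, so the numbers were taken to pair the samples. The slide row follows the same numbers. The fit without a block is the one reported, and a block by number or within each line is an alternative.

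The planned search for miR-125b sites in 3′ untranslated regions needed transcript sequences, which were not used here, and was replaced after seeing the data by a search of the 60-base probe sequences. The strand of the probes was checked with the polyadenylation signal: AATAAA occurs in 2642 of 18789 probes and its complement TTTATT in 794. Heptamers were ranked where at least 20 genes had them. Genes with 4 forms of the site and with its reverse complement were compared with other genes by a permutation test of ranks (100000 draws, two-sided), adjusted over the 15 tests.

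The code was tested on simulated data for 18789 genes with the spread of the real arrays and 50 genes changed at each of 4 sizes per comparison. The simulated noise was independent between arrays and had the same spread in both lines. It lacked the deviations that replicates of the same number share, so the rates may differ in the real data. In 70Z/3 it recovered 0% of changes of 1 log2 unit, 40% of 2, 72% of 3 and 86% of 4, and made 105 calls with 6 false. Averaged over both lines it recovered 30, 74, 92 and 92%, with 152 calls and 8 false. Other settings tried were normexp background correction (offset 50), quantile normalization, the series table, no intensity filter, a filter on all 8 arrays, the mean of a gene's probes, array weights, an intensity trend, an added fold threshold, an additive model, only the 4 arrays compared, and leaving out each array. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.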

Results

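Gene expression was measured in mouse pre-B leukaemia cells that had received a synthetic microRNA. The lines were 70Z/3, a pre-B lymphoblast line, and '18-81', a pre-B line transformed by the Abelson murine leukaemia virus. Cells were transfected with 10 nM of a duplex that releases miR-125b or of a control duplex called miR-Neg, the medium was changed after 8 h and RNA was taken at 48 h. The aim stated for the experiment was to find targets of miR-125b. There were 4 groups with 2 arrays each, from 2 independent experiments, so the 8 arrays limit the precision of every value. Between 38.9 and 45.8% of the probes were well above background on an array, and the dimmest array was replicate 2 of 70Z/3 with miR-Neg (38.9%). The 75th percentile of its intensity was 337.7, against 504.0 to 725.1 on the other 7 arrays and 512.8 on replicate 1 of the same group. In both replicate pairs of 70Z/3 this percentile was lower with miR-Neg than with miR-125b (512.8 against 701.5, and 337.7 against 504.0). The '18-81' pairs were closer (709.5 with miR-Neg against 725.1, and 575.3 against 568.6). In 70Z/3, array brightness and duplex therefore cannot be told apart. Across genes, arrays of a group correlated with r between 0.98 and 0.991, arrays of a line with different duplexes with r between 0.97 and 0.995, and arrays of different lines with r between 0.847 and 0.876. The array does not measure mature miR-125b, so the delivery of the duplex has no check in these values. Log2 differences are given ± standard error of the limma model, in which both lines share the spread of a gene.

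In 70Z/3, the clearest pattern after miR-125b was a rise of the interferon response genes, which cells switch on when they sense viral or foreign RNA. All 27 measured members of the list fixed for this pathway lay above the median of all genes, and their median stood 1.71 log2 units above it, a 3.28-fold difference. The largest differences between miR-125b and miR-Neg included the antiviral enzyme Oas2 (2.92 ± 0.89), the GTPase Mx2 (2.72 ± 1.07), the interferon signalling brake Usp18 (2.70 ± 0.93) and the antiviral protein Rsad2 (2.66 ± 1.17). The transcription factor Irf7 was at 2.27 ± 0.75 and the ubiquitin-like modifier Isg15 at 1.74 ± 0.52. In the control cells 17 of the 27 genes were well above background on both arrays, and after miR-125b all 27 were. Oas2, Mx2, Rsad2 and Irf7 were above it on 1 of the 2 control arrays. The list passed the set test (camera, adjusted p = 3.9e-21), which is lost when the correlation between the genes is estimated (adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone, 12 of the 27 genes were higher, and over all 18789 genes tested 0 were (limma). The 2 replicate pairs differed in size, with medians of 0.82 and 2.22 above all genes. Without the dim miR-Neg replicate 2 the list's median was 0.76 above them. The 2 miR-Neg arrays thus differed from each other in these genes, by an amount close to the rise itself. The size of the rise therefore depends on which control array is used. Of the myeloid markers, Lyz2 and Mpo were well above background in 70Z/3 only after miR-125b, while Csf1r was at −1.41 ± 0.52 and Ctss at −0.69. The Ifit and Oas families hold near-identical copies, so single members are uncertain.

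**Figure D1:**
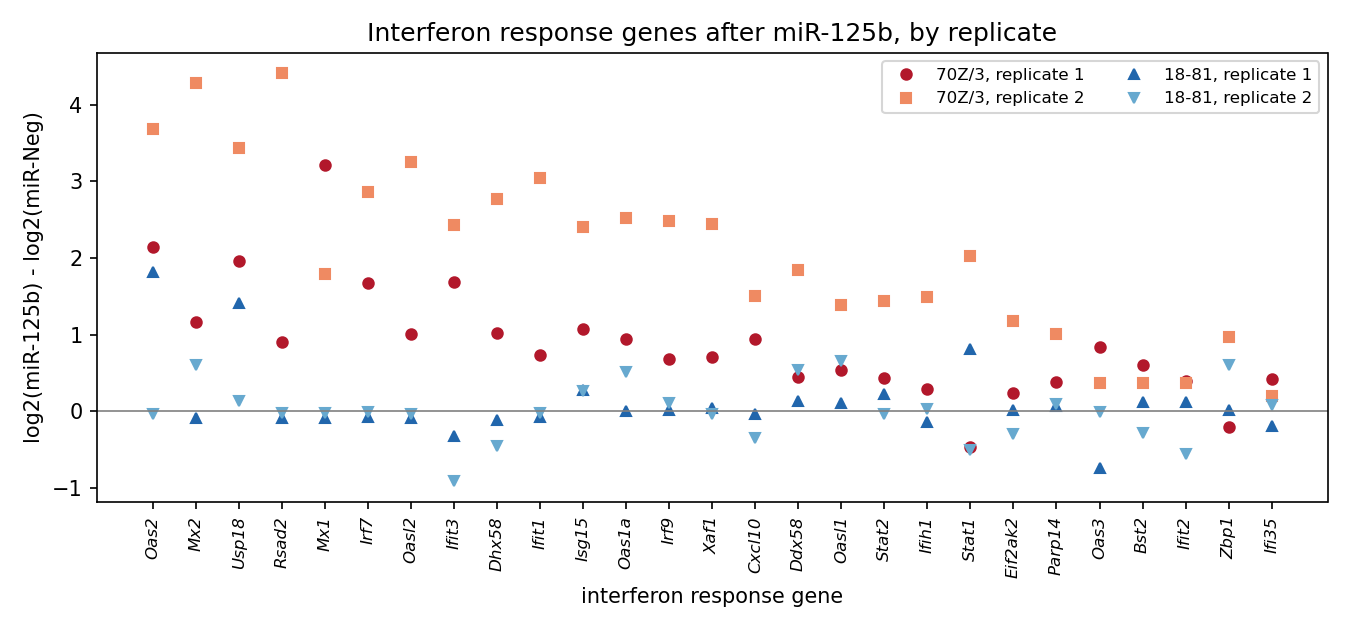
Difference between miR-125b and miR-Neg in log2 intensity (vertical axis) for the 27 measured interferon response genes (horizontal axis), with 1 point per replicate pair in each line. The 70Z/3 points lie mostly above 0, with list medians 0.82 and 2.22 above all genes, and the '18-81' points scatter around 0, with list medians of −0.01 and −0.04.

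Genes of the S-phase list, which make and regulate replicating DNA, fell together in 70Z/3. Of 21 measured members 17 lay below the median of all genes, by a list median of −0.32 (−0.15 and −0.61 in the replicate pairs), and the set test gave an adjusted p = 0.00111 (camera; adjusted p = 0.429 with an estimated correlation). The differences were −1.15 ± 0.31 for the cell cycle transcription factor E2f2, −0.82 ± 0.40 for the replication clamp Pcna and −0.77 ± 0.30 for Uhrf1, which maintains DNA methylation. The NF-kappaB response genes rose by a list median of 0.37 (0.09 and 0.71 in the pairs), with 14 of 17 above all genes (adjusted p = 0.00567; adjusted p = 0.429 with an estimated correlation). Examples were the apoptosis inhibitor Birc3 (0.81 ± 0.38) and the subunit Nfkb2 (0.74 ± 0.34), while the chemokine Ccl3 was at −0.03 and 2.73 in the replicate pairs. The T-cell markers fell by a list median of −0.54, with 8 of 10 below all genes (adjusted p = 0.0248; adjusted p = 0.446 with an estimated correlation). Cd3d was at −1.27 ± 0.69, the kinase Lck at −1.13 ± 0.65 and the kinase Zap70 at −0.99 ± 0.52, while Cd2, Cd3g and Cd8b1 were not well above background in 70Z/3. Adjusted over the list alone, 0 genes of these 3 lists passed in limma, as over all genes. Without the dim miR-Neg replicate 2 of 70Z/3 the adjusted p was 0.534 for the NF-kappaB genes (median 0.10) and 0.106 for the T-cell markers (median −0.26), and without miR-Neg replicate 1 the NF-kappaB median was 0.98. Without miR-125b replicate 2 it was 0.0914 for the S-phase genes, and without miR-125b replicate 1 it was 0.0744 for the T-cell markers. Quantile normalization gave 0.101 for the T-cell markers, and without an intensity filter the adjusted p was 0.121 for the S-phase genes and 0.23 for the T-cell markers.

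No single gene passed in 70Z/3 (0 of 18789 at an adjusted p of 0.05, limma), although 1106 genes had an unadjusted p under 0.05, 525 higher and 581 lower, where chance alone gives 939. With the replicate number as a block the unadjusted count was 3925, and with a block within each line 3999. Without miR-Neg replicate 2 of 70Z/3 the count was 2, Zfp799 and E230029C05Rik, both lower. The smallest unadjusted p among genes higher after miR-125b was that of Sparc, which encodes a matrix-binding glycoprotein (4.64 ± 0.49, 4.60 and 4.68 in the 2 replicate pairs, adjusted p = 0.141, probe at chromosome 11, 55208939 to 55208998, mm9). With the replicate pairs within each line as a block, Sparc was the only gene to pass (adjusted p = 0.0229). Other genes with higher values were the mannose receptor Mrc1 (2.04 ± 0.28), the endosomal GTPase Rab7b (5.26 ± 0.84), the nucleotide receptor P2ry6 (2.42 ± 0.44) and the homeobox gene Rhox5 (1.48 ± 0.28), of which Rab7b and P2ry6 were above background on 1 of the 2 control arrays. Mmp13, Nek6, Mx1 and Mlana were not well above background in control cells and were at least 1.85-fold, 1.71-fold, 1.21-fold and 1.05-fold higher. Among genes lower in value, small unadjusted p-values were those of Rprl2 (−2.44 ± 0.37), Abtb1 (−1.78 ± 0.30), Myl4 (−1.67 ± 0.29), Dus1l (−1.39 ± 0.28) and Arid3a (−1.37 ± 0.28). Slc25a53 was at least 2.19-fold lower. Klra23 (−2.54 ± 0.55) and H2al1e (−1.28 ± 0.28) have close paralogs and are uncertain, and Rab25 and the predicted gene Gm8126 were not well above background in either 70Z/3 group.

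Of 46 measured genes reported as miR-125b targets in other cells, 27 lay below the median of all genes in 70Z/3, by a list median of −0.14 (−0.24 and 0.08 in the replicate pairs; adjusted p = 0.155, and 0.0123 without miR-Neg replicate 2). Adjusted over the list alone 2 were lower, and over all genes 0 were (limma; 4 at an unadjusted p under 0.05). Abtb1, a protein with ankyrin repeats and a BTB domain, was at −1.67 and −1.90 in the replicate pairs (probe at chromosome 6, 88785910 to 88785969, mm9). Arid3a, a transcription factor of the B lineage also called Bright, was at −1.63 and −1.10 (chromosome 10, 79417377 to 79417436). The plasma cell regulator Irf4 was at −1.06 ± 0.31 and the p53 target Trp53inp1 at −1.19 ± 0.38, although a second Trp53inp1 probe gave −0.39. The apoptosis effector Bak1 was at −0.10, Bmf at −0.24, Bbc3 (Puma) at 0.64 and Trp53 at 0.63 ± 0.93. Of the others always reported, Prdm1 was at −0.39 (−0.60 and −0.18 in the pairs). Values that did not pass were also measured for Tnfaip3 (−0.31), Ets1 (−0.30), Tet2 (−0.21), Stat3 (0.00), Arid3b (0.26) and Lin28a (0.37). Lin28b was below the intensity filter.

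The remaining lists did not pass in 70Z/3. Median distances from all genes were 0.31 for the p53 pathway (adjusted p = 0.155), −0.20 for apoptosis regulators (0.235), −0.11 for B-cell precursor genes (0.273), −0.26 for plasma cell differentiation (0.188) and −0.05 for G2/M genes (0.289). They were −0.10 for Myc and nucleolar genes (0.264), 0.39 for microRNA pathway genes (0.155), −0.14 for the unfolded protein and stress response (0.591), 0.14 for cholesterol synthesis (0.235) and 0.27 for glycolysis (0.0791). With the replicate number as a block the adjusted p was 0.0464 for the microRNA pathway and 0.0473 for glycolysis, and with a block within each line 0.0469 for glycolysis, which also passed without miR-Neg replicate 2 (0.0432) and under 6 alternatives of normalization, filter or intensity trend (0.000282 to 0.0435). With normexp the p53 pathway (0.0267), the microRNA pathway (0.0472) and cholesterol synthesis (0.0149) passed too, the last 2 also without the intensity filter (0.0153 and 0.0266). In the p53 list the cell cycle inhibitor Cdkn1a was at 1.22 ± 0.34. Among markers of other cell types, the stromal list had 2 measured genes (median 2.26, adjusted p = 0.0625, with 0.00412 without miR-Neg replicate 2, 0.0247 without miR-125b replicate 2 and 0.00697 to 0.0435 under 3 alternatives of background, filter or trend), of which Sparc was at 4.64 and Vim at −0.38, and the erythroid list 4 (−0.25, 0.546). The 8 myeloid markers had a median of 0.35 (adjusted p = 0.253). The lysozyme gene Lyz2 and Mpo were not well above background in control cells and were above it on both arrays after miR-125b. Adjusted over the list alone, Sparc of the stromal list and Lyz2 of the myeloid list were higher, and over all genes 0 were (limma).

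**Figure D2:**
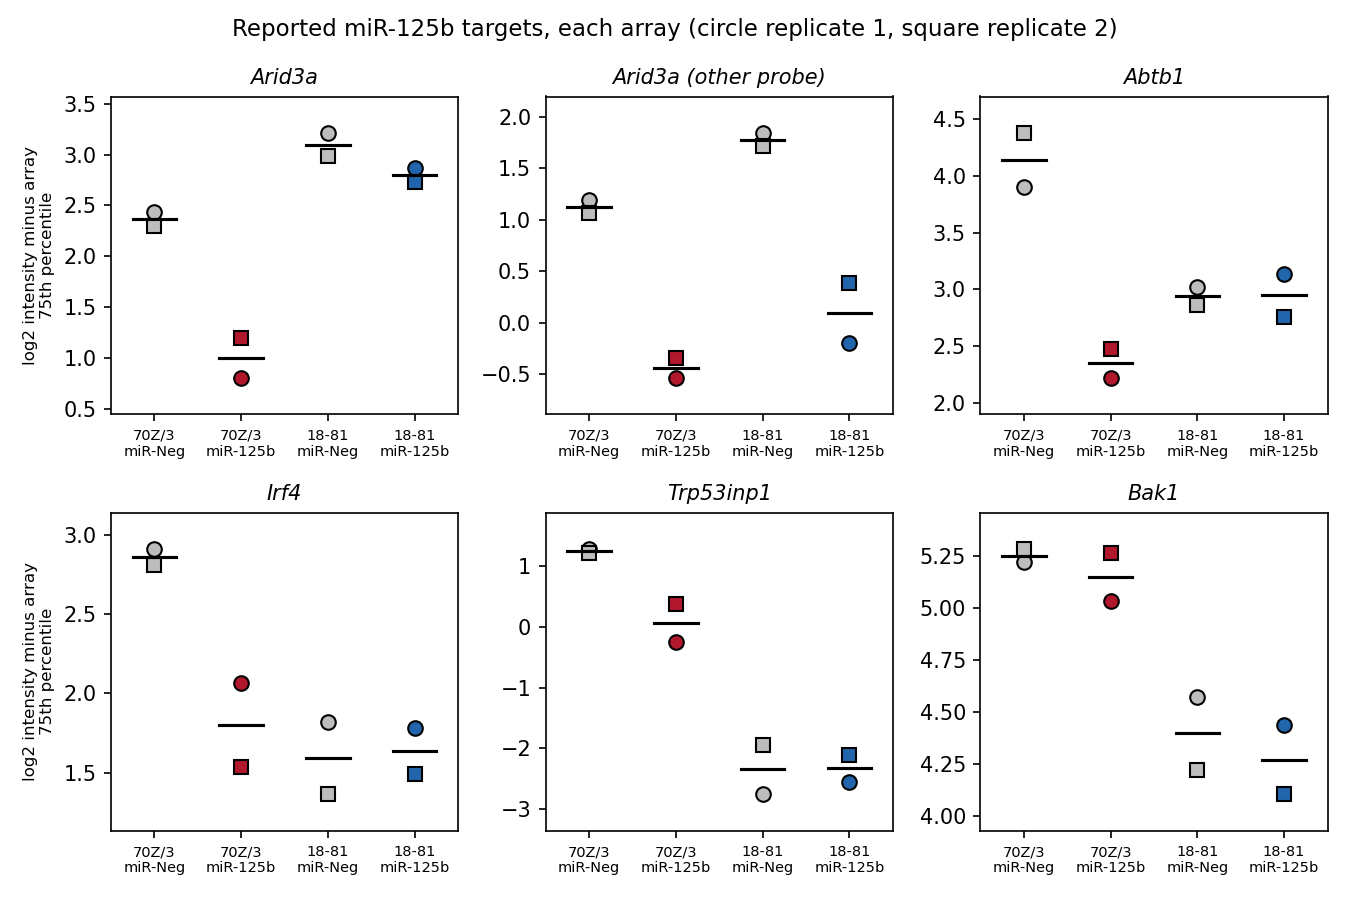
Intensity of each array on the log2 scale relative to its 75th percentile (vertical axis) in the 4 groups (horizontal axis) for 2 Arid3a probes, Abtb1, Irf4, Trp53inp1 and Bak1, with circles for replicate 1, squares for replicate 2 and lines for the group means. The second Arid3a probe was lower after miR-125b in both lines, by −1.56 and −1.68, while Abtb1 differed by −1.78 in 70Z/3 and 0.00 in '18-81'.

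In '18-81' the gene lists stayed close to the other genes after miR-125b. The interferon response genes had a median of −0.07 relative to all genes (adjusted p = 0.992, camera), and the reported targets one of −0.02 (adjusted p = 0.405, and 0.0372 without miR-Neg replicate 2). Of the 18 lists, the stromal markers alone passed, on 2 measured genes (median −0.75, adjusted p = 0.00867; adjusted p = 0.57 with an estimated correlation). These go opposite ways, with vimentin, Vim, at −1.68 and Sparc at 0.23, so the median describes neither. With the replicate number as a block that adjusted p was 0.113, and with a block within each line 0.426. It was 0.244 without miR-Neg replicate 1, 0.205 without miR-125b replicate 1 and 0.182 without miR-125b replicate 2 of '18-81'. No gene passed (0 of 18789, limma), and 228 had an unadjusted p under 0.05, 113 higher and 115 lower. Under the 2 blocks the counts were 528 and 582, all below the 939 that chance alone gives. The fit gives both lines 1 spread per gene, while the log2 differences had a standard deviation of 0.321 in '18-81' and 0.547 in 70Z/3. A count under 939 therefore does not show that no gene changed. The self-test recovered 78% of simulated changes of 3 log2 units in this comparison and 46% of those of 2 units. Without miR-125b replicate 2 of '18-81' the count was 9, without replicate 1 it was 5, and without miR-Neg replicate 2 it was 1.

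The smallest adjusted p in '18-81' was 0.133, for genes that include the secreted protein gene Srpx2 (−2.50 ± 0.28, probe at chromosome X, 130466293 to 130466352, mm9) and the olfactory receptor gene Olfr1496, at least 2.95-fold higher. Further genes with low values were Cfap300 (−3.10 ± 0.38), the POU factor Pou3f1 (−2.53 ± 0.42, above background on 1 of 2 arrays after miR-125b), the selenophosphate synthetase Sephs2 (−2.09 ± 0.35) and vimentin, Vim (−1.68 ± 0.32). P3h1 was at −2.80 ± 0.39, but another of its probes gave 0.22. Ctbs was at least 6.71-fold lower. Among genes with high values, the leukotriene synthase Ltc4s was at 4.05 ± 0.70, and Lmtk3, Vmn1r52, Hhat, Alx4, Defb30 and Marveld1 were at least 3.24-fold, 2.39-fold, 2.17-fold, 2.07-fold, 1.67-fold and 1.26-fold higher, with Marveld1 above background on 1 array. The predicted genes Gm7822 (−2.34), Gm15644 (−1.63) and Gm9246 (at least 2.1-fold lower) and the transcript 1700047M11Rik (at least 1.34-fold higher) were further members, with Samd4, which has no fold because neither group was well above background. Of the genes always reported, Bak1 was at −0.13, Trp53 at −0.59, Prdm1 at −0.51, Ets1 at −0.37, Irf4 at 0.04 and Trp53inp1 at 0.02.

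Averaged over both lines, the reported targets had a slightly lower median than all genes, in a call that many alternatives lost. The replicate pairs were at −0.242 and 0.076 in 70Z/3 and at −0.076 and −0.065 in '18-81'. The list median lay −0.06 from all genes, 28 of 46 were below, and the set test gave an adjusted p = 0.0374 (camera; adjusted p = 0.428 with an estimated correlation). Adjusted over the list alone 0 genes passed, as over all genes (limma; 3 lower at an unadjusted p under 0.05). Arid3a was among the genes with the smallest unadjusted p in this average (−0.83 ± 0.20), with −0.35 and −0.25 in the '18-81' pairs at its brightest probe. A second Arid3a probe, chosen after its values were seen, gave −1.56 ± 0.30 in 70Z/3, −1.68 ± 0.30 in '18-81' and −1.62 ± 0.21 on average (chromosome 10, 79417698 to 79417757, mm9; adjusted p = 0.538 over 25301 probes, limma). The call of the target list was lost with the replicate number as a block (adjusted p = 0.0815) and with a block within each line (0.0501). The adjusted p (camera) was 0.0558 with normexp, 0.069 with quantile normalization, 0.0616 with the series table and 0.904 without the intensity filter. With fry the adjusted p of the target list was 0.342. Over the fits without 1 array the median of the target list ran from −0.155 to −0.055.

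The interferon response genes also passed in the average (median 0.80, 27 of 27 above all genes, adjusted p = 5.25e-19; adjusted p = 0.428 with an estimated correlation), as did the S-phase genes (−0.16, adjusted p = 0.00731; 0.428 as adjusted p with an estimated correlation) and the NF-kappaB genes (0.16, adjusted p = 0.045; 0.428 as adjusted p with an estimated correlation). These averages came from 70Z/3. In '18-81' alone the medians were −0.07 for the interferon genes (12 of 27 above all genes), 0.03 for the S-phase genes and −0.09 for the NF-kappaB genes. Without 70Z/3 miR-Neg replicate 2 the interferon median of the average was 0.32, and without 70Z/3 miR-Neg replicate 1 the S-phase median was −0.27. For the NF-kappaB genes the adjusted p was 0.0643 and 0.0699 with the 2 blocks and 0.908 without 70Z/3 miR-Neg replicate 2. It was also above 0.05 without any of 6 other arrays, between 0.0587 and 0.199, and their median ran from 0.05 to 0.38 over the fits without 1 array. For the S-phase genes it was 0.239 without '18-81' miR-Neg replicate 1, 0.187 without 70Z/3 miR-125b replicate 2 and 0.13 without '18-81' miR-125b replicate 2. No gene passed in the average (0, limma; 508 at an unadjusted p under 0.05, 273 higher and 235 lower, against 939 by chance and 1388 and 1562 under the 2 blocks), and 5 did without '18-81' miR-125b replicate 2, 1 without replicate 1 and 1 without miR-Neg replicate 2. The averages were low for Pou3f1 (−1.71 ± 0.29, with −0.14 in 1 of the 70Z/3 pairs), the ubiquitin ligase Ube4a (−0.83 ± 0.20), the autophagy protease Atg4d (−1.33 ± 0.32) and Tmed9 (−0.92 ± 0.23). High values in both lines were measured for the drug transporter Abcb1a (0.85 ± 0.19) and the interferon-induced membrane protein Ifitm3 (0.89 ± 0.22), while the average of Mrc1 (1.05 ± 0.20) came from 70Z/3, with 0.10 and 0.01 in the '18-81' pairs.

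The files hold 60-base probe sequences, and 83 genes had the miR-125b seed match CTCAGGG in their probe. Their median difference from other genes was −0.04 in 70Z/3, −0.01 in '18-81' and −0.09 on average. The adjusted p over these 3 tests was 0.0635, 0.786 and 0.0635 (camera), and 0.0449 in 70Z/3 and on average without 70Z/3 miR-Neg replicate 2. This search was chosen after seeing the data, with 5 motifs looked at, and covers the probe and not the whole 3′ untranslated region. In a two-sided permutation test of ranks, which takes genes as independent and is adjusted over 15 tests of the 5 motifs, CTCAGGG passed on average (adjusted p = 0.0118). The other forms did not in any of the 3 comparisons, where the largest median difference was −0.32 for CTCAGGGA in 70Z/3 (23 genes, permutation test, adjusted p = 0.0762). On average TCAGGGA was at −0.02 (79 genes, permutation test, adjusted p = 0.257), CTCAGGGA at −0.01 (adjusted p = 0.257) and TCAGGG at −0.03 (257 genes, permutation test, adjusted p = 0.0762). CCCTGAG, which is the reverse complement and no form of the site, was higher in '18-81' by 0.05 (106 genes, permutation test, adjusted p = 0.0118). Ranked among 12151 heptamers from the lowest z score of the mean difference, the site stood at 188 on average (z = −2.72), 226 in 70Z/3 (z = −2.69) and 6291 in '18-81' (z = 0.01). The lowest z scores were those of CCGCCCC in 70Z/3 (−10.98), GAAGAAG in '18-81' (−6.60) and GTGTGTG on average (−6.88).

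The effect of miR-125b differed between the lines for 5 lists, by the test of the difference itself. Relative to all genes, the effect in '18-81' minus that in 70Z/3 was −1.63 for the interferon response genes (adjusted p = 4.98e-16; adjusted p = 0.382 with an estimated correlation) and −0.62 for the NF-kappaB genes (adjusted p = 0.00772; adjusted p = 0.487 with an estimated correlation). It was 0.30 for the S-phase genes (adjusted p = 0.00266; adjusted p = 0.487 with an estimated correlation) and 0.64 for the T-cell markers (adjusted p = 0.0213; adjusted p = 0.592 with an estimated correlation). The 2 stromal markers differed by −3.02 (adjusted p = 1.62e-05; adjusted p = 0.205 with an estimated correlation), which includes Sparc (−4.41 ± 0.70). The median difference of all genes was 0.16 with the 75th percentile and 0.01 after quantile normalization, and the list values are relative to it. No gene passed (0, limma; 606 at an unadjusted p under 0.05, against 939 by chance and 2422 and 2424 under the 2 blocks). The glycolysis genes did not pass as reported (−0.33, adjusted p = 0.069) and did under the blocks (0.0344 and 0.0276) and 7 alternatives of normalization, filter, probe or trend (0.000312 to 0.0367). The gene count was 5 without '18-81' miR-125b replicate 2 and 1 without '18-81' miR-Neg replicate 2. The genes with the smallest unadjusted p that were measured in all groups were Cfap300 (−3.45 ± 0.54), Srpx2 (−2.45 ± 0.39), Mrc1 (−1.99 ± 0.39), Ltc4s (4.86 ± 0.99) and Rprl2 (2.75). Olfr1496, Defb30, Mlana and Pifo also ranked there, but were not well above background in 2 or more of the 4 groups and have no size of difference. The self-test recovered 22% of simulated differences of 3 log2 units here, and 0% of those of 2.

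Several of these calls or their sizes rested on single arrays. The interferon difference was −0.64 without 70Z/3 miR-Neg replicate 2 and −2.47 without miR-Neg replicate 1, and the list passed in both. The S-phase difference was 0.51 without 70Z/3 miR-125b replicate 1 and 0.45 without miR-Neg replicate 1, and the NF-kappaB difference −0.96 without miR-Neg replicate 1. Without 70Z/3 miR-Neg replicate 2 the adjusted p of the difference was 0.471 for the NF-kappaB genes (difference −0.23) and 0.11 for the T-cell markers (difference 0.31). For the T-cell markers it was also 0.0623 without 70Z/3 miR-125b replicate 1, 0.0598 without '18-81' miR-Neg replicate 2 and 0.0729 without '18-81' miR-125b replicate 2. For the S-phase genes it was 0.11 without '18-81' miR-125b replicate 1, 0.13 without 70Z/3 miR-125b replicate 2 and 0.143 without '18-81' miR-Neg replicate 2. Across genes, which are not independent replicates, the effects of miR-125b in the lines correlated with Pearson r = −0.152 and Spearman rho = −0.2. Between single replicate pairs of the lines r ran from −0.25 to 0.057, and within a line it was 0.412 in 70Z/3 and 0.106 in '18-81'. The correlation of the lines was −0.018 without 70Z/3 miR-Neg replicate 2, 0.039 without '18-81' miR-Neg replicate 1, −0.324 without '18-81' miR-125b replicate 1 and 0.203 without '18-81' miR-125b replicate 2. Of genes with an unadjusted p under 0.05 in each line, 3 were higher in both (3.2 by chance) and 5 lower in both (3.6 by chance).

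The lines themselves differed widely under miR-Neg. Of 18789 genes 4058 differed (21.6%; limma, adjusted p under 0.05), 1849 higher in '18-81' and 2209 higher in 70Z/3, and 3956 of them by at least 2-fold. The largest differences with both lines measured included the homeobox gene Rhox5 (11.15 ± 0.28 higher in '18-81'), H2-Eb1 of the MHC class II (9.28 ± 0.32), the plasma cell chaperone Mzb1 (8.77 ± 0.38) and the cytokine signalling inhibitor Socs1 (6.92 ± 0.40). Cd74, the MHC class II invariant chain (11.59 ± 0.56), and the fetal serum protein Afp (11.17 ± 0.38) were also higher in '18-81', with 1 of 2 control arrays of 70Z/3 above background. The isocitrate dehydrogenase Idh2 was at least 1260-fold and Cish, a target of cytokine signalling, at least 1250-fold higher in '18-81', followed by Gtsf1, Emilin2, Wfdc15a and Chac1 (at least 967-, 692-, 663- and 512-fold). In 70Z/3 the asparagine synthetase Asns was at least 6850-fold higher (adjusted p = 1.41e-06, probe at chromosome 6, 7625171 to 7625228, mm9). Ppic, Ramp1, Egfl7, the transferrin gene Trf, Plpp2, the cyclin D1 gene Ccnd1, Rhoj, Skap1 and Ydjc were at least 2730-, 1750-, 1440-, 1260-, 1140-, 629-, 531-, 519- and 384-fold higher in 70Z/3, although other probes of Ramp1 gave differences down to −3.73 log2 units. Among genes measured in both lines, a ranking chosen after the values were seen, the antiviral Oasl1 (−8.48 ± 0.31 in '18-81'), Cnn3 (−9.34) and galectin 1, Lgals1 (−8.04 ± 0.32) were higher in 70Z/3. In 852 of the 1849 and 849 of the 2209 genes, the lower line was not well above background on either array, so folds there are bounds. With the replicate number as a block 6826 genes differed, and 6740 with a block within each line.

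Of 31 measured B-cell precursor genes, 5 were higher and 12 lower in '18-81', and the list as a whole did not pass (median −0.63 relative to all genes, adjusted p = 0.211, camera; 0.0118 with fry, which does not compare a list with other genes). The genes higher in '18-81' included the transcription factors Spib (4.26 ± 0.34), Irf8 (2.54 ± 0.26) and Foxo1 (0.88) and the coactivator Pou2af1 (1.34). Lower in '18-81' were Cd72 (−4.21 ± 0.48), Bcl6 (−3.44 ± 0.67), the DNA nucleotidyltransferase Dntt (−3.01 ± 0.64), Cd93 (−2.04 ± 0.31) and Myb (−1.99 ± 0.41). The surrogate light chain genes Igll1 (−2.96 ± 0.48), Vpreb1 (−2.11 ± 0.39) and Vpreb2 (−1.95 ± 0.46) were lower as well, of which the last 2 are near-identical copies and uncertain. Lef1 (−1.76), Sox4 (−1.64), Cd79b (−1.31) and the interleukin 7 receptor Il7r (−1.28) completed the 12. Of these, Bcl6, Dntt, Myb and Vpreb2 lost the call under some of the alternatives. Of 14 plasma cell differentiation genes 6 were higher in '18-81' and 3 lower (median 0.53, adjusted p = 0.167, with 0.00153 without the intensity filter and 0.0138 with fry). The immunoglobulin joining chain Jchain was at least 258-fold and Slamf7 at least 21.2-fold higher, and Cd38 (3.46 ± 0.39) and Ell2 (2.44 ± 0.38) were higher. Creb3l2 was at least 11.7-fold lower, and syndecan 1, Sdc1 (−3.22 ± 0.30), and Irf4 (−1.27 ± 0.31) were lower.

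**Figure D3:**
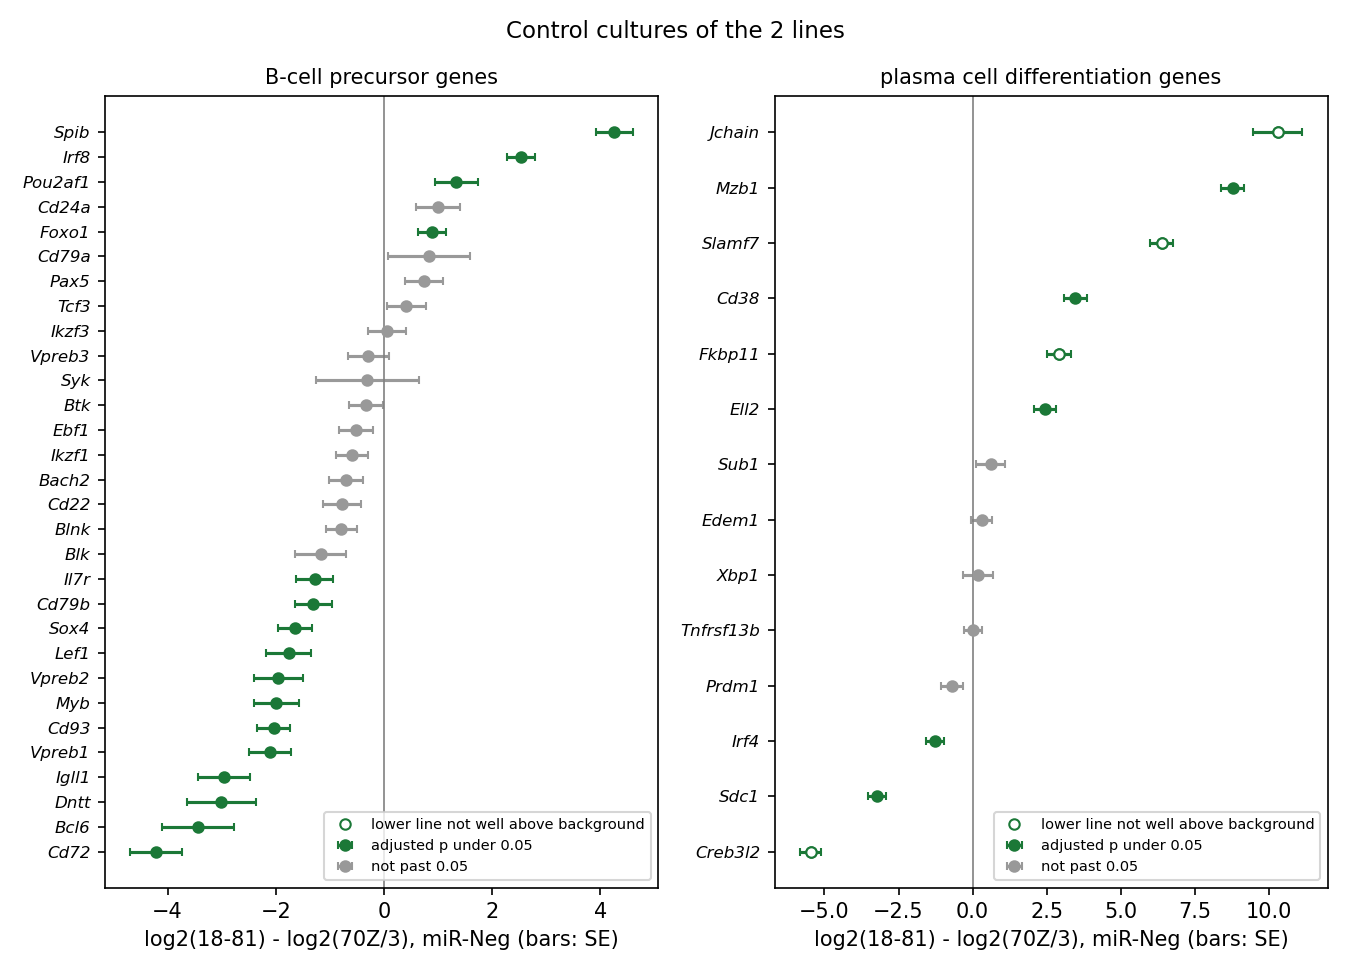
Difference between '18-81' and 70Z/3 under miR-Neg in log2 intensity with its standard error (horizontal axis) for the B-cell precursor genes reported here (left) and plasma cell differentiation genes (right), green where the adjusted p is under 0.05 and grey where it is not, with open circles where the lower line was not well above background. In the left panel 4 genes lie to the right past the threshold and 12 to the left, and in the right panel 6 and 3.

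The interferon response genes were the list that passed between the control cultures. Relative to all genes their median was −1.54 in '18-81' against 70Z/3 (adjusted p = 0.000143, camera; adjusted p = 0.581 with an estimated correlation), 23 of 27 lay below, and 14 of 27 were lower over all genes. The median was −0.99 without 70Z/3 miR-Neg replicate 1 and −2.48 without replicate 2, so the control arrays of 70Z/3 differed from each other in these genes. The RNA sensors Ddx58 (−3.20) and Ifih1 (−3.53) and the chemokine Cxcl10 (−3.81, above background on 1 of 2 arrays in '18-81') were lower, Usp18 at least 16.4-fold, Oasl2 at least 7.35-fold and Irf7 at least 4.45-fold. In '18-81' control cells 15 of the 27 genes were well above background on both arrays. Other lists held single genes with large differences. In the p53 list 2 genes were higher and 6 lower in '18-81', with Cdkn1a at least 88.9-fold lower and Trp53inp1 at −3.60. Of the apoptosis regulators 2 were higher and 4 lower, with Bcl2l2 at least 18.8-fold higher. Of the reported targets 7 were higher and 4 lower. G2/M (4 higher, 0 lower), glycolysis (4 higher, 0 lower) and S-phase genes (0 higher, 2 lower) did not pass as lists (adjusted p = 0.148, 0.126 and 0.234). Glycolysis passed between the lines under 5 alternatives of normalization and filter (adjusted p from 0.0011 to 0.0146) and the G2/M genes under 3 (0.00131 to 0.0331). Without the intensity filter the reported targets (0.0132) and cholesterol synthesis (0.0492) passed as well.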

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

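The tests of myeloid cells and of the duplex itself were chosen only after the result was seen. The test of the difference of effects, the estimated correlation and the fits without single arrays were planned. The random lists, the removal of probe trends and the comparison by replicate number address patterns seen in the data, so they are not counted as planned.

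The effect of miR-125b differed between '18-81' and 70Z/3 for 5 gene lists, by the test of the difference itself. The adjusted p (camera) was 4.98e-16 for the interferon response genes, 0.00266 for the S-phase genes, 0.00772 for the NF-kappaB response genes, 0.0213 for the T-cell markers and 1.62e-05 for the stromal markers. With an estimated correlation between genes none of the 5 passed, and the lowest adjusted p was then 0.205, for the stromal markers. The stromal list rests on 2 measured genes, of which Sparc was at 4.64 ± 0.49 in 70Z/3 and 0.23 in '18-81'. Among the T-cell markers, Cd2, Cd3g and Cd8b1 were not well above background in 70Z/3, where a change in the array's 75th percentile alone moves the value. That percentile was higher with miR-125b than with miR-Neg in both 70Z/3 pairs, which lowers such values after miR-125b.

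The interferon response genes stood 1.71 log2 units above all genes after miR-125b in 70Z/3, 0.76 without the dim 70Z/3 miR-Neg replicate 2, and −0.067 from them in '18-81'. That 1 array decides the call at the preset correlation, which is lost with an estimated correlation in all 8 arrays (adjusted p = 0.429), is argued against by the highest adjusted p over the leave-one-out fits, 8.02e-14, reached without that array, although the size depends on it, and a bias that follows brightness is argued against by 10000 random lists matched on level, of which the highest median was 0.51 against 1.58 for the list (percentile 100). The random lists were matched on the mean over all 8 arrays and took genes as independent. Many members are dimmer in '18-81', so the lists were not matched on brightness in 70Z/3. Myeloid cells in the 70Z/3 cultures stay open. The 8 myeloid markers had a median of 0.353, under 0.856, the limit set for a median that goes against them. The markers split, with 4 above and 4 below all genes (Lyz2 and Mpo above background only after miR-125b, Csf1r at −1.41 and Ctss at −0.69). Their upper quartile, 0.912, a criterion added to the one set, passes that limit, so the median was not taken to decide. An innate response to the duplex may also contribute. The same duplexes gave −0.067 in '18-81', and 0.036 over the 15 genes above background on all 4 of its arrays. In control cells 15 of the 27 genes were well above background on both arrays in '18-81', against 17 in 70Z/3. These counts do not decide whether '18-81' could lack the response, and miR-Neg is a duplex too. A response of 70Z/3 to miR-125b as such is a hypothesis that no value here separates from the open explanations.

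Across genes the effects of miR-125b in the lines correlated negatively (r = −0.152). Trends on GC content and level of the probes are argued against as the cause, since r was −0.157 after their removal. Leaving out the dim 70Z/3 miR-Neg replicate 2 moved r to −0.018, as a fault of that array would predict, so the negative sign may come from it. The correlation was also 0.039 without '18-81' miR-Neg replicate 1 and 0.203 without '18-81' miR-125b replicate 2, so it does not belong to the dim array alone. A shift shared by arrays of a replicate number stays open, with a difference of −0.088 between same-numbered and other pairs.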

How the results depend on the processing

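The combined setting, the search for the seed match in the probes and the histone set were chosen after seeing the data, and the other alternatives were planned. Of the gene list results under the alternatives 1560 stayed on their side of the threshold, 79 lost and 70 gained the call, and 1 was reversed. A change of direction was counted as a reversal only where the reported or the alternative result passed, so the 1560 include changes of direction among results that did not pass. Of the results on named genes 6559 were kept, 26 gained and 7 lost the call (Dntt, Myb, Vpreb2 and Bcl6 between the lines). No gene passed for miR-125b or for the difference of effects, so named genes there had no call to lose. A change of direction counted as kept where neither unadjusted p was under 0.05. Of the counts 86 stayed within 1.5 times the reported one and 18 moved. The dim array limits values near background, which shift with the 75th percentile. The cause was not tested where a value below differs, unless stated. A lone array left in a group was assumed to vary like the other groups. The planned analysis of seed sites in 3′ untranslated regions was not run, with its site classes, choice of region, region lengths, control sites and heptamer ranking.

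With an estimated correlation between genes no list passed. The adjusted p was then 0.429 in 70Z/3 for the interferon, S-phase and NF-kappaB genes, 0.446 for the T-cell markers, 0.428 on average for the interferon, S-phase, NF-kappaB and reported target genes and 0.57 for the stromal markers in '18-81'. For the difference of effects it was 0.382 (interferon), 0.487 (S-phase and NF-kappaB), 0.592 (T-cell) and 0.205 (stromal), and 0.581 for the interferon genes between the lines. With fry it was 0.136 (interferon), 0.12 (S-phase) and 0.254 (NF-kappaB, T-cell) in 70Z/3, 0.342 on average for the interferon, S-phase and target genes, 0.518 for NF-kappaB, and 0.986 for the stromal markers in '18-81'. For the difference of effects fry gave 0.393 (interferon), 0.275 (S-phase), 0.49 (NF-kappaB, T-cell) and 0.082 (stromal). Between the lines fry reversed the stress response genes, to lower in '18-81' (0.0463), and 10 lists gained the call (0.0114 to 0.0463), among them the p53 (0.0114), apoptosis and B-cell precursor (0.0118), plasma cell and G2/M genes (0.0138). fry does not compare a list with other genes, by its construction.

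With normexp 1 gene passed in 70Z/3 (Sparc, adjusted p = 0.0266), and the target list was at 0.0558 on average. Quantile normalization gave 0.101 for the T-cell markers in 70Z/3 and, on average, 0.069 for the targets and 0.0902 for NF-kappaB, and the seed match passed in 70Z/3 and on average (0.029 for each). The series table gave 0.0886, 0.0616 and 0.106 for these lists and 0.0261 for each seed match. Without the intensity filter, the S-phase genes were at 0.121 in 70Z/3, 0.259 on average and 0.192 for the difference, the T-cell markers at 0.23 and 0.187, the stromal markers in '18-81' at 0.985 and the targets at 0.904. With all 8 arrays above background, 1872 of 14656 genes differed between the lines, where fewer genes were tested, and the T-cell markers were at 0.0727. Under alternatives of normalization, filter, probe or trend, glycolysis gained the call in 70Z/3 (6 alternatives, 0.000282 to 0.0435), on average (4, 0.00902 to 0.0377), for the difference (7, 0.000312 to 0.0367) and between the lines (5, 0.0011 to 0.0146). In 70Z/3 the p53 (0.0267 with normexp), microRNA pathway (0.0472 with normexp, 0.0153 without the filter), cholesterol (0.0149, 0.0266) and stromal lists (3, 0.00697 to 0.0435) gained it. For the difference the p53 (0.039 with normexp), cholesterol (0.0235 with normexp, 0.0417 without the filter) and microRNA pathway lists (0.0417 without the filter) did. On average the plasma cell (3, 0.0247 to 0.05) and G2/M lists (0.0441 with the mean of probes) did, and between the lines G2/M (3, 0.00131 to 0.0331) and, without the filter, the targets (0.0132), plasma cell (0.00153) and cholesterol lists (0.0492).

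With the replicate number as a block, 6826 genes differed between the lines, and the adjusted p was 0.113 for the stromal markers in '18-81', 0.0815 for the targets and 0.0643 for NF-kappaB on average. With a replicate block within each line, 6740 genes differed, 1 gene passed in 70Z/3 (Sparc), and the lists were at 0.426, 0.0501 and 0.0699. Glycolysis gained the call with the 2 blocks in 70Z/3 (0.0473 and 0.0469) and for the difference (0.0344 and 0.0276), the microRNA pathway in 70Z/3 with the number (0.0464) and the plasma cell genes on average within lines (0.023). The 2 blocks changed no other call of a list and no other count past the adjusted threshold. Unadjusted counts were 3925 and 3999 in 70Z/3, 528 and 582 in '18-81', 1388 and 1562 on average, 2422 and 2424 for the difference and 8918 and 8853 between the lines, against 1106, 228, 508, 606 and 6154 without a block. A block within each line, joined with all 8 arrays above background and an intensity trend, gave 315 genes in 70Z/3 (51 higher, 264 lower), 23 in '18-81', 1 on average (Sparc) and 5 for the difference. It was chosen after 24 combinations of normalization, filter, block and trend had been seen, over which the count in 70Z/3 ran from 0 to 762 and was above 0 in 10.

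Over the fits that leave out 1 array, the counts ran from 0 to 2 in 70Z/3 (2 without miR-Neg replicate 2), 0 to 9 in '18-81', 0 to 5 on average, 0 to 5 for the difference and 2767 to 4000 between the lines, and the correlation of the lines from −0.324 to 0.203. The difference gave 5 without '18-81' miR-125b replicate 2 and 1 without miR-Neg replicate 2. The adjusted p for the interferon genes ran from 1.14e-23 to 8.02e-14 in 70Z/3, 4.33e-25 to 1.55e-10 on average, 3.37e-22 to 1.78e-09 for the difference and 2e-10 to 0.0311 between the lines. For the S-phase genes it ran from 2.07e-05 to 0.0914 in 70Z/3, 0.000366 to 0.239 on average and 9.94e-05 to 0.143 for the difference, and for NF-kappaB from 0.000813 to 0.534, 0.00367 to 0.908 and 0.00104 to 0.471. For the T-cell markers it ran from 0.0165 to 0.106 in 70Z/3 and 0.0274 to 0.11 for the difference, for the targets from 0.00171 to 0.355 on average, and for the stromal markers from 0.0145 to 0.244 in '18-81' and 6.3e-08 to 0.00578 for the difference. For the seed match it ran from 0.0449 to 0.155 in 70Z/3, 0.268 to 0.919 in '18-81' and 0.0183 to 0.353 on average, with 0.0449 without 70Z/3 miR-Neg replicate 2 and 0.0183 without '18-81' miR-Neg replicate 2.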

Other observations

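The histone set, the combined setting, the search of the probe sequences and the comparison over genes above background in '18-81' were chosen only after the result was seen.

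Many histone genes, which are expressed in S phase, lay below all genes in 70Z/3, as the S-phase list did, and no test here separates the sets. In the combined setting (a block within each line, all 8 arrays above background and an intensity trend), 22 of the 39 histone genes tested were lower after miR-125b in 70Z/3 and 0 were higher. Over all 14656 genes tested there, 264 were lower and 51 higher, so calls in this setting were mostly lower in general. In the fit reported above, 35 of 42 lay below all genes in 70Z/3, by a median of −0.59, with 7 of 42 below in '18-81' (median 0.14). The difference of the lines had a camera p = 5.41e-07 and a p = 0.347 with an estimated correlation, so the genes do not count as independent. Their sequences are near-identical, so single members are uncertain. In the same combined setting, 5 of 41 reported targets were lower in 70Z/3, Abtb1, Arid3a, Irf4, Mknk2 and Ppp1ca, and 0 were higher. The S-phase genes E2f2 and Pcna, Irf4 and Mzb1 of the plasma cell list were lower, while Dhx58 and Isg15 of the interferon list, Dntt and Sparc were higher. The setting was picked after its counts were seen, and with quantile normalization in its place the count in 70Z/3 was 12.

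The interferon response genes that '18-81' does express also lay close to all genes there after miR-125b. Of the 15 genes above background on all 4 of its arrays, 8 lay above the median of all genes, with a median of 0.04, while in 70Z/3 all 15 lay above, with a median of 1.07. In the '18-81' control cells 10 of the 27 genes were below background on both arrays, against 3 of 27 in 70Z/3.

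The hypothesis that genes with the seed match fall through that match was tested with the rank of CTCAGGG among 12151 heptamers of the probes. On average over both lines the site stood at rank 188 from the lowest, within the lowest 1.55%, and in '18-81' it stood at 51.8%, so the test leaves it open whether repression through the seed could be seen.

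Other splits of the 8 arrays into groups of 4 were run for the average effect, in a model with the line. At an adjusted p of 0.05 the real split gave 0 genes (limma), so that all 34 splits gave as many by construction and the count says nothing, and the highest of the others gave 3313. At an unadjusted p of 0.05 the real split gave 345 genes, 22 of the 34 splits gave as many and the highest other gave 7364, so chance cannot be excluded for that count. The split with 3313 and 7364 genes is the one by replicate number, which is also the slide row, and its size points to a structure of the samples by experiment or by row. With the replicate number as a block, 0 genes passed for the average over both lines (limma), and 1388 had an unadjusted p under 0.05. Of the 8 splits that part all 4 replicate pairs, 3 gave as many genes as the real one, itself included, and the highest other gave 654.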
